A study of Mus musculus with 6 samples.

How the data were processed

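Gene expression was measured by RNA sequencing in primary hepatic stellate cells from mouse liver on days 1, 4 and 7, with 2 libraries per day and 6 libraries in all. The labels number the day 1 libraries 2 and 3, and the day 4 and day 7 libraries 1 and 2, and those numbers are used here as names only. The labels do not say from what event the days were counted, or whether the libraries of a day came from separate cultures or animals. Per the labels' protocols, RNA was isolated with TRIzol, ribosomal RNA was removed, and stranded total RNA libraries were made from 1.3 µg of RNA each.

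The authors' deposited values are TPM (transcript abundances scaled to a fixed library total), given once per gene symbol and library. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2 2.0.5 and StringTie 1.3.3b, with the mouse genome builds mm10 and GRCm38. The role of each tool, the gene annotation, the use of strand in quantification and the way transcripts were summed to genes are not given in the sources used here. TPM is a share of each library's total, so a few very abundant transcripts lower the TPM of every other gene in that library. TPM keeps no record of sequencing depth, so the depth of each library is unknown, and no counting error or detection limit was computed. A deposited list of genes of the glycolysis pathway and a deposited sheet of gene types were also used. The labels name no batch, so no comparison within a batch was possible.

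The table held 35999 symbols, of which 10841 were at 0 in every library. In GENCODE release M21, on GRCm38, 35880 of the symbols (99.7%) matched exactly 1 gene, and the coordinates given come from that release. Predicted gene models that shared at least 10% of their 20-base words with the model Gm10800 were grouped as satellite-like models, because these loci are known to carry pericentromeric satellite repeat sequence. There were 12 such models. This group was defined after the most abundant genes of each library had been seen.

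Genes with at least 1 TPM in at least 2 of the 6 libraries were tested, which left 14373 genes. Values were transformed as log2(TPM + 1), so a log2 change understates the change of genes with low TPM. A linear model with day as a factor was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that followed a mean trend and were robust to outlying genes. All 6 libraries shared 1 estimate of the spread, with 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were called. A moderated F test over the 3 days used the same fit.

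Before the data were examined, 35 gene lists were fixed, 23 of pathways or cell states and 12 of markers of other cell types. They named 754 genes, of which 682 were tested. Each list with at least 3 tested members was set against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 35 lists. The same test with an estimated correlation and the test fry served as alternatives. Named genes were chosen by a rule fixed in advance. It took the 8 largest increases and 8 largest decreases per comparison among called genes with both libraries of one day above both of the other and at least 5 TPM on the higher day, leaving out predicted and small RNA models. It added the 3 called members of each list with the largest change, or the 2 most abundant members where none was called. It also added Acta2, Col1a1, Col1a2, Lrat, Reln, Des, Pdgfrb, Timp1 and Mki67. Results of some genes that the rule took are not reported here.

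The alternatives planned in advance were other pseudocounts, no filter and a stricter filter on low values, other scalings, a plain variance model, a 2-fold threshold, a term for the replicate number, a fit of only the days compared, and leaving out each library in turn. Rescaling without the satellite-like models, library weights per day and list tests on only the days compared were added after the data had been seen. Tests for read counts, planned in case counts were present, were not run because the table holds TPM. The fit was tested on simulated data for day 4 against day 1, in 10 runs with 200 of the 14373 genes changed. It called 5.4% of genes changed by 0.5 on the log2 scale, 65.8% of those changed by 1 and 96.2% of those changed by 2. Of all calls 7.6% were false, which is above the rate that the adjusted p threshold aims at. The data gave 5257 calls for day 4 against day 1, so a call in the simulation needed a smaller unadjusted p. These percentages therefore do not give the power of the reported fit. Medians of 2 lists were compared with 100000 random reassignments of their genes and 2000 bootstrap draws. Both treat genes as independent and do not measure the spread between libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.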

Results

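Hepatic stellate cells are the vitamin A-storing pericytes of the liver sinusoid, and on activation they become contractile, matrix-producing myofibroblasts. The series followed the gene expression of primary mouse stellate cells during activation, on days 1, 4 and 7. Each day had 2 libraries, and the values below are means ± SD over those 2 libraries (n = 2) unless stated otherwise. The p-values measure only the spread between these libraries, which may be technical, since no label says that they came from separate cultures or animals. Between 19854 and 21604 symbols were above 0 per library, and depth is unknown.

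Day 1 stood apart from the later days. Across the 14373 tested genes, Pearson correlations of log2(TPM + 1) were 0.880 to 0.919 between day 1 and day 4 libraries, 0.865 to 0.900 between day 1 and day 7, and 0.978 to 0.980 between day 4 and day 7. Correlations within a day were 0.970 on day 1, 0.986 on day 4 and 0.986 on day 7, so the 2 day 1 libraries resembled each other less than day 4 resembled day 7. The first principal component held 75.4% of the variance and separated day 1 from both later days. The within-day SD of log2(TPM + 1) was 0.37 on day 1, 0.26 on day 4 and 0.254 on day 7.

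**Figure D1:**
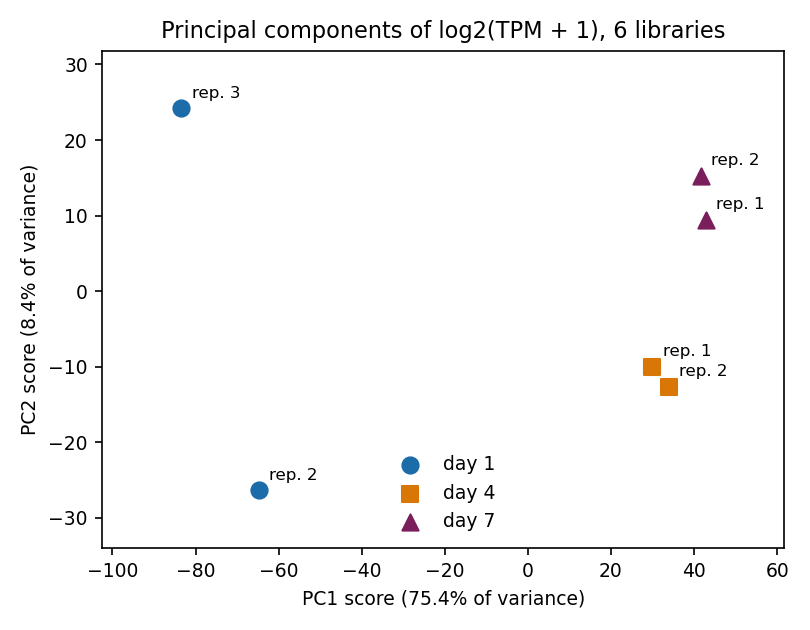
First and second principal components of log2(TPM + 1) over the tested genes, in arbitrary component units, with 1 point per library coloured by day. The 2 day 1 libraries lie at -64.74 and -83.47 on the first component, while the 4 later libraries lie between 29.91 and 42.78.

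The composition of the day 1 libraries differed in a group of 12 satellite-like gene models. They took 17.4% of all TPM in day 1 replicate 2 and 26.2% in replicate 3, against 0.06% to 0.09% in the 4 later libraries. Gm10800 alone, on chromosome 2 from 98666547 to 98667301 in GRCm38, took 13.6% and 20.7% on day 1. TPM of all other genes are lower on day 1 by that share. Ccnb1ip1, whose model overlaps the RNase P RNA gene Rpph1 on the same strand, took 3.14% to 3.65% of TPM on day 1 and 7.06% to 8.07% later, so its value may hold reads of both genes. Ccdc107, which overlaps Rmrp on the opposite strand, is uncertain in the same way, with 0.642% to 0.733% on day 1 and 1.73% to 2.24% later.

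**Figure D2:**
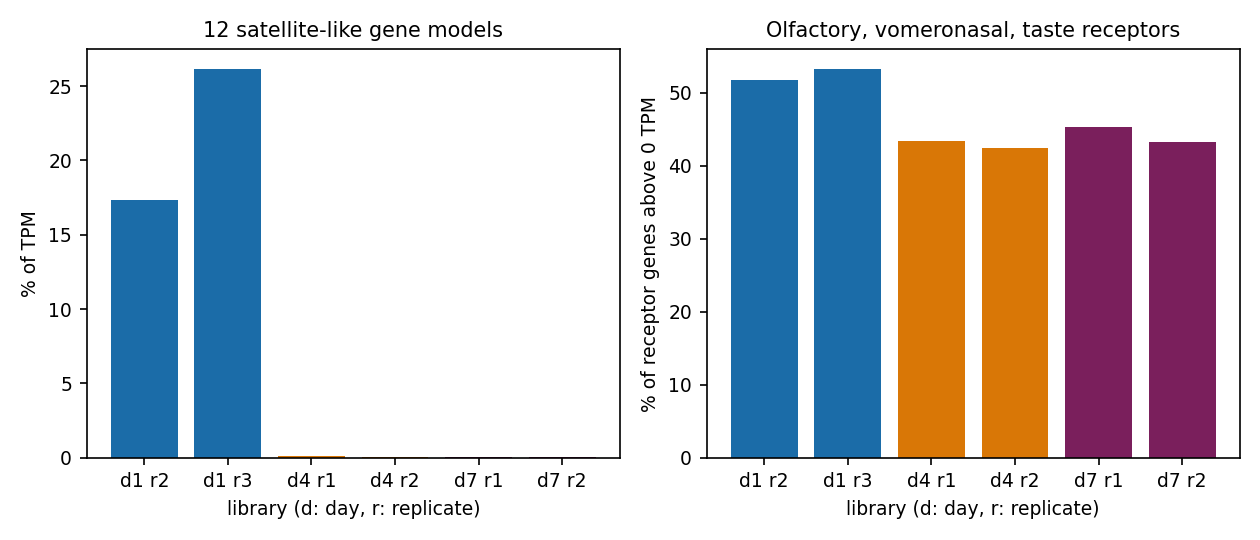
Left, share of TPM in the 12 satellite-like gene models, and right, share of 1777 olfactory, vomeronasal and taste receptor genes listed above 0 TPM, both in percent with 1 bar per library coloured by day. Satellite-like models hold 17.4% and 26.2% on day 1 and 0.06% to 0.09% later, and receptor genes above 0 make up 51.7% and 53.3% on day 1 and 42.5% to 45.3% later.

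The comparison of day 4 with day 1 addressed the first interval of the series. Macrophage markers had a median of 394 TPM on day 1, against 42.7 TPM for the myofibroblast and contractile genes. These medians do not measure shares of cells. Macrophage marker RNA was not limited to day 1, since Lyz2 of that list ranked 5 to 8 by TPM in every later library (7379.2 to 10992.9 TPM). Which cells the changes below came from was not tested. Contractile genes of the myofibroblast rose, with Acta2 in the lead. Acta2, which encodes alpha smooth muscle actin and lies on chromosome 19 from 34241090 to 34255590, rose from 2.47 ± 0.57 to 484 ± 28 TPM. Its log2 change was 7.14 (SE 0.14, limma adjusted p = 7.6e-06). The myosin light chain gene Myl9 rose from 3.02 ± 1.6 to 240 ± 7.1 TPM, and the tropomyosin gene Tpm2 from 2.81 ± 0.22 to 144 ± 2.7 TPM. The matrix genes Spon2 (0.72 ± 0.11 to 148 ± 0.58 TPM) and Ogn (0.276 ± 0.019 to 52.6 ± 2.9 TPM) were also among the 8 largest increases, with log2 changes of 6.43 and 5.39. Among called genes that are not predicted models, the antiviral gene Rsad2 on chromosome 12 from 26442746 to 26456452 had the largest decrease, from 437 ± 22 to 8.53 ± 0.048 TPM.

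By limma, 5257 of 14373 genes were called between day 4 and day 1, 3590 higher and 1667 lower on day 4, and 6941 genes had an unadjusted p under 0.05. The direction of the majority depended on the scaling, with 2779 higher and 2331 lower after median-ratio scaling, 2839 and 2504 after quantile normalization, and 2060 and 3468 after rescaling without the satellite-like models. The median log2 change of all genes was 0.11 as deposited, -0.02 under either of the first 2 scalings and -0.22 without the satellite-like models, so changes of that size are not read as a direction here. Leaving out day 4 replicate 1 or 2, which left 1 library on that day, gave 2311 or 2196 genes.

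Of the 30 myofibroblast and contractile genes, 26 rose and none fell, and 27 rose when adjusted over the list alone. Their median log2 change was 2.20, which passed the list test at the preset correlation (camera adjusted p = 8.33e-13) but not with an estimated correlation (adjusted p = 0.0606). Without the satellite-like models 24 rose and the median was 1.86. Among collagens and collagen-processing genes, 29 of 31 rose and none fell, the same number adjusted over the list alone (median 1.91, adjusted p = 3.25e-13, or adjusted p = 0.0838 with an estimated correlation). Col5a2 rose from 5.13 ± 0.71 to 366 ± 9.5 TPM, Col3a1 from 4.33 ± 0.13 to 231 ± 7.8 TPM, and the collagen cross-linking enzyme gene Lox from 0.483 ± 0.019 to 34.7 ± 0.64 TPM. The type I collagen genes rose less, Col1a1 by 2.26 (SE 0.23) and Col1a2 by 2.35 (SE 0.2) on the log2 scale. Of 16 basement membrane genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with Col4a5 at 3.37 and Nid2 at 3.21, and the list test gave adjusted p = 0.00534, or adjusted p = 0.0589 without day 1 replicate 2 and adjusted p = 0.303 with an estimated correlation. Metalloproteinases and their inhibitors went both ways, 7 higher and 6 lower of 19 (10 and 6 adjusted over the list alone, camera adjusted p = 0.769), with the inhibitor gene Timp1 up by 3.46 and Mmp10 up by 3.06. Of the markers of other cells, 15 of 23 of macrophages and 7 of 9 of mesothelium also rose, with tests given below.

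Proliferation genes rose together. Of the 36 cell cycle genes 35 rose and none fell, and all 36 rose when adjusted over the list alone. The median was 2.36 with camera adjusted p = 1.36e-18, or adjusted p = 0.0606 with an estimated correlation, and 32 rose without the satellite-like models. Beside this and the other rising groups, 15 of 23 macrophage and 7 of 9 mesothelial markers rose. Mki67 rose from 1.27 ± 0.18 to 21.2 ± 0.13 TPM, the cyclin gene Ccnb1 from 1.1 ± 0.0011 to 27.2 ± 2.4 TPM, and the topoisomerase gene Top2a from 4.32 ± 1.3 to 67.3 ± 3.6 TPM. Among cell cycle inhibitors and p53 targets, 7 of 20 rose and 2 fell, the same numbers adjusted over the list alone (adjusted p = 0.364), and the median of 0.18 became -0.17 without the satellite-like models. The largest increase there was Cdkn2c, a CDK inhibitor gene, at 2.17.

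Genes of the quiescent stellate cell went in both directions. Of 25 measured, 11 rose and 4 fell, the same numbers adjusted over the list alone, with a median of 0.56 (camera adjusted p = 0.112). Without the satellite-like models the counts were 8 and 5 and the median was 0.23, which passed against the then lower median of all genes (adjusted p = 0.0297), as did the list without day 4 replicate 1 (adjusted p = 0.0457). Members that rose included the intermediate filament gene Des (6.19 ± 0.081 to 44.1 ± 1.8 TPM) and Lrat, the retinol esterifying enzyme gene (0.494 ± 0.0037 to 5.99 ± 0.5 TPM). Plin2, a member that fell, is given with the lipid genes below. Reln rose from 11.1 ± 2.1 to 20.3 ± 1.3 TPM with limma adjusted p = 0.0099, but missed the threshold without day 4 replicate 1 (adjusted p = 0.0766), without day 4 replicate 2 (adjusted p = 0.0549) and without the satellite-like models (log2 change 0.49, adjusted p = 0.0939). Of 20 retinoid genes 11 rose and 1 fell (11 and 3 adjusted over the list alone), which missed the list threshold (camera adjusted p = 0.0536) but passed without day 1 replicate 3, day 4 replicate 1 or day 4 replicate 2 (adjusted p = 0.0458, 0.0332 and 0.0474). It also passed after median-ratio scaling, without the satellite-like models and with library weights per day (camera adjusted p = 0.0214, 0.00475 and 0.0366). Aldh1a1, a retinaldehyde dehydrogenase gene, rose by 4.50, and the carotene oxygenase gene Bco1 by 3.50.

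Of 31 growth factor and receptor genes, 23 rose and 3 fell (24 and 3 adjusted over the list alone), with camera adjusted p = 1.49e-05, or adjusted p = 0.0838 with an estimated correlation. Bmp4 rose by 4.03 and Pdgfd by 3.30, while the endothelin receptor gene Ednrb fell from 422 ± 73 to 35.1 ± 0.56 TPM. The PDGF receptor gene Pdgfrb rose by 2.07 (SE 0.14). Of 22 YAP and TEAD targets 13 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.00205, or adjusted p = 0.303 with an estimated correlation), with the tissue factor gene F3 up by 2.75. In the TGF-beta pathway 15 of 27 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.0597, or 0.0458 without day 1 replicate 3, 0.0474 without day 4 replicate 2, 0.034 after median-ratio scaling and 0.0102 without the satellite-like models), with Tgfb3 up by 3.29. Mesenchymal transcription factor genes numbered 8 higher and 3 lower of 24 (9 and 4 adjusted over the list alone, adjusted p = 0.893), and Hand2 rose by 2.00. Integrin and focal adhesion genes numbered 11 higher and 1 lower of 28, the same adjusted over the list alone (adjusted p = 0.165, or 0.00849 without day 1 replicate 3), with a median of 0.21 that became -0.14 without the satellite-like models.

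Interferon response genes fell. Of 28 measured, 25 fell and none rose, and 27 fell when adjusted over the list alone. The median was -2.33 with camera adjusted p = 6.91e-22, or adjusted p = 0.0838 with an estimated correlation, and all 28 fell after rescaling without the satellite-like models. Isg15, a ubiquitin-like modifier gene, fell from 376 ± 120 to 16.2 ± 0.57 TPM, and Ifit3 fell from 740 ± 97 to 34.7 ± 3.6 TPM. Ifit3 and Ifit3b, and likewise Ms4a4a and Ms4a4c, are close relatives, so reads may have been split between them and their values are uncertain. Cytokine, chemokine and NF-kB target genes numbered 6 higher and 15 lower of 29 (7 and 15 adjusted over the list alone, median -0.35, adjusted p = 0.00108, or adjusted p = 0.271 with an estimated correlation). The chemokine gene Cxcl10 fell from 340 ± 54 to 16.6 ± 0.94 TPM, Cxcl1 from 275 ± 120 to 19.8 ± 3.1 TPM and Ccl5 from 90.7 ± 15 to 6.49 ± 2.1 TPM. Immediate early and heat shock genes numbered 1 higher and 14 lower of 26 (1 and 15 adjusted over the list alone, adjusted p = 6.79e-06, or adjusted p = 0.0838 with an estimated correlation), with the cytokine signalling inhibitor gene Socs3 at -1.52 and the small heat shock protein gene Hspb1 at 1.52 on the log2 scale. Beside these groups, 7 of 9 dendritic cell markers and 3 of 12 T and NK cell markers fell, and 15 of 23 macrophage markers rose, and these lists did not pass camera with an estimated correlation (adjusted p = 0.303, 0.303 and 0.519).

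**Figure D3:**
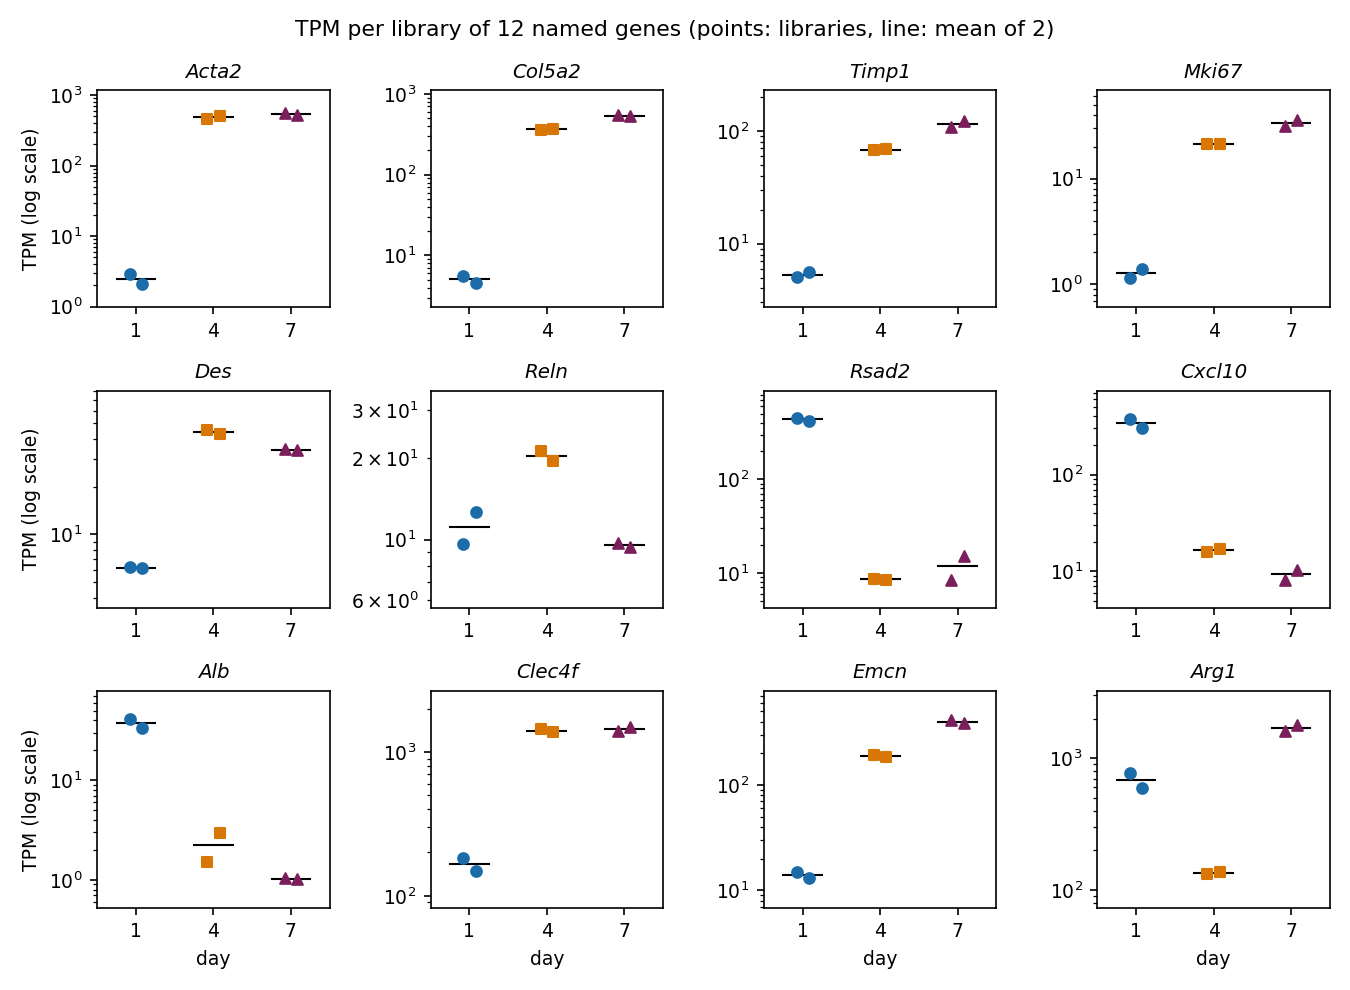
TPM of 12 named genes by day, each on its own log axis, with 1 point per library and a line at the mean of the 2 libraries of a day. Acta2 goes from 2.47 to 484 and 535 TPM, Rsad2 from 437 to 8.53 and 11.7 TPM, and Arg1 from 681 to 135 and 1690 TPM.

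Among metabolic and housekeeping lists, several rose as deposited and gave lower counts without the satellite-like models. Cholesterol synthesis genes numbered 18 higher and none lower of 24, the same adjusted over the list alone (median 0.68, adjusted p = 0.000164, or adjusted p = 0.131 with an estimated correlation), and 10 rose without the satellite-like models. Ribosomal protein genes numbered 24 higher and none lower of 30 (26 and none adjusted over the list alone, adjusted p = 0.000106, or adjusted p = 0.519 with an estimated correlation), and 10 rose without those models. Oxidative phosphorylation genes numbered 15 higher and none lower of 25 (20 and 1 adjusted over the list alone, adjusted p = 0.00108, or adjusted p = 0.519 with an estimated correlation), and 3 rose and 1 fell without those models. Glycolysis genes numbered 12 higher and 2 lower of 19 (14 and 2 adjusted over the list alone, adjusted p = 0.0044, or adjusted p = 0.303 with an estimated correlation), with the lactate transporter gene Slc16a3 up by 1.62 and Pdk1 by 1.56. In the glycolysis list deposited with the series 21 of 48 rose and 3 fell (26 and 3 adjusted over the list alone), but the study chose that list and it is not independent evidence of a direction. Lipid storage and synthesis genes numbered 9 higher and 1 lower of 23, the same adjusted over the list alone (adjusted p = 0.146). The fatty acid transporter gene Cd36 rose from 359 ± 59 to 1050 ± 9.7 TPM, and the 1 that fell was Plin2, a lipid droplet coat gene named after its value was seen, from 1400 ± 270 to 690 ± 11 TPM. Its log2 change of -1.01 became -0.99 and -1.02 without day 4 replicate 1 or 2, which left 1 library on that day and no call (limma adjusted p = 0.0647 and 0.0618). ER chaperone and secretion genes numbered 13 higher and 3 lower of 28 (13 and 6 adjusted over the list alone, adjusted p = 0.376), with a median of 0.32 that became -0.04 without the satellite-like models. Mitochondrially encoded genes numbered 4 higher and none lower of 13, the same adjusted over the list alone (adjusted p = 0.642), with a median of 0.22 that became -0.14 without those models.

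Markers of other liver cell types moved in different directions. Of the macrophage markers 15 of 23 rose and 2 fell (15 and 3 adjusted over the list alone, median 0.86, camera adjusted p = 0.00445, or adjusted p = 0.519 with an estimated correlation). The Kupffer cell lectin gene Clec4f rose from 165 ± 24 to 1410 ± 55 TPM, and the lysozyme gene Lyz2 from 1160 ± 350 to 7390 ± 15 TPM. Without the satellite-like models 13 rose and 4 fell. Hepatocyte markers numbered 1 higher and 13 lower of 16 (2 and 13 adjusted over the list alone, adjusted p = 6.79e-06, or adjusted p = 0.303 with an estimated correlation), and Alb fell from 37.3 ± 5 to 2.22 ± 1 TPM. Mesothelial markers numbered 7 higher and none lower of 9 (9 and none adjusted over the list alone, adjusted p = 0.00087, or adjusted p = 0.303 with an estimated correlation), with Upk3b up by 3.03. Endothelial markers numbered 7 higher and 2 lower of 22 (10 and 6 adjusted over the list alone, adjusted p = 0.405), with a median of 0.22 that became -0.12 without the satellite-like models. The endothelial sialomucin gene Emcn rose from 14 ± 1.4 to 188 ± 5.2 TPM. Dendritic cell markers numbered 1 higher and 7 lower of 9, the same adjusted over the list alone (adjusted p = 4.33e-05, or adjusted p = 0.303 with an estimated correlation), and the invariant chain gene Cd74 fell from 962 ± 55 to 250 ± 36 TPM.

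Of 12 T and NK cell markers 3 fell and none rose, the same adjusted over the list alone (camera adjusted p = 0.0268, or 0.0762 without day 1 replicate 2, 0.0767 without the satellite-like models and adjusted p = 0.303 with an estimated correlation), with the granzyme gene Gzmb at 18.5 ± 5.2 and 2.44 ± 0.29 TPM. B and plasma cell markers numbered 1 higher and 3 lower of 4, the same adjusted over the list alone (adjusted p = 0.0536, or 0.0474 without day 4 replicate 2), with Igkc at 49.8 ± 0.82 and 12.5 ± 1 TPM. Erythroid markers numbered 2 lower of 3, the same adjusted over the list alone (adjusted p = 0.0419, or 0.104 without day 1 replicate 2, 0.105 without the satellite-like models, 0.0633 after median-ratio scaling, 0.0619 with a pseudocount of 0.1, 0.0533 with library weights per day and adjusted p = 0.303 with an estimated correlation), and the hemoglobin gene Hba-a2, one of near-identical copies, was listed at 0 in both day 4 libraries. No neutrophil marker of 4 was called by limma on all genes or adjusted over the list alone (camera adjusted p = 0.454), 1 had an unadjusted p under 0.05, and S100a8 was at 7.56 ± 3.2 and 9.66 ± 4.7 TPM. Cholangiocyte markers numbered 3 higher and 1 lower of 6, the same adjusted over the list alone (adjusted p = 0.69), portal fibroblast markers 6 and 2 of 11 (7 and 2 adjusted over the list alone, adjusted p = 0.166, or 0.0264 without the satellite-like models), and smooth muscle markers 5 and none of 8 (5 and 1 adjusted over the list alone, adjusted p = 0.0562, or 0.0318 and 0.0295 without day 4 replicate 1 or 2, 0.029 after median-ratio scaling and 0.00547 without the satellite-like models). Fbln2, a portal fibroblast marker, rose by 3.51, and the smooth muscle myosin gene Myh11 rose by 2.73.

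The comparison of day 7 with day 1 covered the whole time course. Acta2 reached 535 ± 22 TPM on day 7, Col5a2 541 ± 4.2 TPM, Timp1 115 ± 10 TPM and Mki67 33.5 ± 3.3 TPM. The log2 changes from day 1 were 7.28, 6.47, 4.19 and 3.92. Sprr1a, a cornified envelope protein gene, rose from 0.852 ± 0.77 TPM on day 1 to 69.3 ± 5.7 TPM. Hist1h3g rose to 113 ± 1.3 TPM, which is uncertain because histone genes are near-identical copies. Cyp1a1, a target of the aryl hydrocarbon receptor, fell from 241 ± 16 to 6.83 ± 0.55 TPM, with a log2 change of -4.95 (SE 0.11, limma adjusted p = 9.7e-06). The interferon regulatory factor gene Irf7 fell from 940 ± 72 to 42.2 ± 6.7 TPM.

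By limma 5956 genes were called, 3546 higher and 2410 lower on day 7, and 7401 had an unadjusted p under 0.05. The split was 3161 and 2827 after median-ratio scaling, 3108 and 2954 after quantile normalization, and 2187 and 4631 without the satellite-like models, so the direction of the majority again depended on the scaling. Leaving out day 7 replicate 1 or 2 gave 2684 or 2717 genes. In the lists, 25 of 30 myofibroblast genes rose and none fell (26 and 2 adjusted over the list alone), as did 28 of 31 collagen genes (29 and none adjusted over the list alone). All 36 cell cycle genes rose, and 27 of 28 interferon response genes fell (all 28 adjusted over the list alone). These 4 lists had camera adjusted p from 7.87e-19 to 9.6e-13, and adjusted p = 0.0577 to 0.0888 with an estimated correlation. Glycolysis genes numbered 15 higher and 1 lower of 19 (16 and 1 adjusted over the list alone, adjusted p = 4.95e-05, or adjusted p = 0.239 with an estimated correlation), with Tpi1, the triosephosphate isomerase gene, up from 187 ± 37 to 747 ± 20 TPM. In the deposited glycolysis list, which the study chose, 26 of 48 rose and 2 fell. Quiescence genes numbered 8 higher and 7 lower of 25 (9 and 7 adjusted over the list alone, camera adjusted p = 0.939), and Reln was at 9.52 ± 0.23 TPM against 11.1 ± 2.1 on day 1 (limma adjusted p = 0.34, or 0.0466 and lower on day 7 without day 1 replicate 2).

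Markers of other cell types moved beside these groups between day 7 and day 1. Macrophage markers numbered 13 higher and 1 lower of 23, the same adjusted over the list alone (camera adjusted p = 0.00955, or adjusted p = 0.51 with an estimated correlation). All 9 mesothelial markers rose, the same adjusted over the list alone (adjusted p = 8.18e-05, or adjusted p = 0.258 with an estimated correlation). Smooth muscle markers numbered 5 higher and none lower of 8, the same adjusted over the list alone (adjusted p = 0.02, or 0.139 without day 1 replicate 2 and adjusted p = 0.239 with an estimated correlation). Hepatocyte markers numbered 1 higher and 13 lower of 16 (2 and 14 adjusted over the list alone, adjusted p = 4.95e-05, or adjusted p = 0.314 with an estimated correlation). Dendritic cell markers numbered 1 higher and 7 lower of 9, the same adjusted over the list alone (adjusted p = 0.000165, or adjusted p = 0.258 with an estimated correlation). T and NK cell markers numbered none higher and 5 lower of 12 (1 and 7 adjusted over the list alone, adjusted p = 0.00199, or adjusted p = 0.152 with an estimated correlation). B and plasma cell markers numbered 1 higher and 3 lower of 4 (camera adjusted p = 0.0239, or 0.0804 without the satellite-like models and 0.258 with an estimated correlation). All 3 erythroid markers fell (camera adjusted p = 0.02, or 0.0574 without the satellite-like models and 0.239 with an estimated correlation). The B and plasma cell and erythroid medians were -2.16 and -1.74, or -2.06 and -1.39 without day 1 replicate 2, which left 1 library on that day.

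The comparison of day 7 with day 4 addressed the later interval. Arg1, the arginase gene on chromosome 10 from 24915221 to 24927484, rose most, from 135 ± 1.9 to 1690 ± 120 TPM, and had been at 681 ± 130 TPM on day 1. Its log2 change was 3.64 (SE 0.17, limma adjusted p = 0.0066). Spp1, the osteopontin gene, rose from 121 ± 1.3 to 648 ± 40 TPM and the coagulation factor XIII subunit gene F13a1 from 2.5 ± 0.024 to 24.1 ± 0.41 TPM. Gpnmb, a gene of the macrophage list, rose from 157 ± 3.8 to 544 ± 33 TPM. It was the 1 macrophage marker of 23 called higher, and none was lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.743). Which cells these changes came from was not tested. The prostaglandin synthase gene Ptgs2 rose from 9.83 ± 0.19 to 27.9 ± 1.9 TPM, the acute phase gene Saa3 from 195 ± 5.7 to 490 ± 19 TPM and F3 from 61.7 ± 0.4 to 162 ± 0.64 TPM. Igkc, the immunoglobulin kappa constant gene, fell from 12.5 ± 1 to 2.64 ± 0.43 TPM and Cyp1a1 from 20.8 ± 0.91 to 6.83 ± 0.55 TPM. By limma 67 genes were called, 44 higher and 23 lower on day 7, and 1705 had an unadjusted p under 0.05. The split was 49 and 13 after median-ratio scaling and 30 and 7 after quantile normalization. The count was 4 without day 4 replicate 1, 0 without day 4 replicate 2, day 7 replicate 1 or day 7 replicate 2 (unadjusted counts 987, 1021 and 868), 510 without day 1 replicate 2 and 546 without day 1 replicate 3. A fit of only the day 4 and day 7 libraries called 609 genes, 265 higher and 344 lower, among them all 67, and 4 genes were called without a filter on low values. Leaving out a later library leaves 1 on its day and fewer residual degrees of freedom, so for the same spread the error of a difference is wider. The log2 changes of the named genes moved little, between 3.57 and 3.71 for Arg1 (limma adjusted p = 0.0576 to 0.3), 2.35 and 2.48 for Spp1, and -2.02 and -1.77 for Igkc, while none of the genes named above kept its call.

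Few matrix genes were called in this interval. By limma none of 31 collagen genes rose and 1 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.726), and 1 of 16 basement membrane genes rose and none fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.00264, or adjusted p = 0.341 with an estimated correlation). At an unadjusted p under 0.05, 4 collagen genes were higher and 3 lower, and 4 basement membrane genes were higher and 1 lower. Col3a1 fell from 231 ± 7.8 to 128 ± 2.1 TPM, while Col4a5 rose from 10.6 ± 0.074 to 31.2 ± 1.8 TPM and Fbln2 from 39 ± 0.46 to 100 ± 3.7 TPM. Of the endothelial markers, Emcn rose from 188 ± 5.2 to 400 ± 17 TPM and Bmp2 fell from 27.7 ± 2.4 to 9.87 ± 1.2 TPM. Rgs5, a pericyte marker in the quiescence list, fell from 8.66 ± 0.41 to 3.07 ± 0.19 TPM at the threshold (limma adjusted p = 0.0496). Without any one of the 4 later libraries these 6 calls were lost (limma adjusted p from 0.223 to 0.451), while the log2 changes stayed close, for example -0.89 to -0.82 for Col3a1 and 1.30 to 1.38 for Fbln2. Acta2, Col1a1, Col1a2, Lrat, Des, Pdgfrb, Timp1, Mki67 and Reln were not called, and the log2 differences nearest to a call were 0.74 for Timp1 (limma adjusted p = 0.066) and -1.02 for Reln (limma adjusted p = 0.068). Without day 1 replicate 2 or 3 these became 0.0208 and 0.0203 for Timp1, and 0.0165 and 0.0156 for Reln, and Mki67, at a log2 difference of 0.64, went from limma adjusted p = 0.151 to 0.0473 and 0.0472. With only the 2 days compared, the limma adjusted p was 0.0166 for Timp1, 0.0147 for Reln and 0.0353 for Mki67, and with library weights per day 0.00614, 0.00467 and 0.0214.

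Between day 4 and day 7 camera called 14 of 35 lists, with medians from -0.85 to 0.61, and part of them are given here. Glycolysis genes had a median of 0.36 (camera adjusted p = 1.2e-10, or adjusted p = 0.118 with an estimated correlation), with no member called over all genes by limma, 8 of 19 higher when adjusted over the list alone and 10 higher at an unadjusted p under 0.05. Quiescence genes had a median of -0.35, with 1 of 25 lower and 10 lower when adjusted over the list alone (camera adjusted p = 0.00015, or adjusted p = 0.118 with an estimated correlation). Endothelial markers had a median of -0.33, with 1 higher and 1 lower of 22 (2 and 10 adjusted over the list alone, camera adjusted p = 9.45e-06, or adjusted p = 0.118 with an estimated correlation). B and plasma cell markers had a median of -0.85, with 1 of 4 lower and all 4 lower when adjusted over the list alone (adjusted p = 3.94e-05, or adjusted p = 0.118 with an estimated correlation). T and NK cell markers had a median of -0.65, with none of 12 called (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.00159, or adjusted p = 0.134 with an estimated correlation). Cholangiocyte markers had a median of 0.61, with none of 6 called (2 higher adjusted over the list alone, adjusted p = 8.55e-05, or adjusted p = 0.118 with an estimated correlation). Myofibroblast genes had a median of 0.12 with 1 of 30 higher, which was Spp1, and 5 adjusted over the list alone (adjusted p = 8.55e-05, or adjusted p = 0.118 with an estimated correlation). Cytokine, chemokine and NF-kB target genes had a median of -0.30, with 2 higher and none lower of 29 (2 and 12 adjusted over the list alone, adjusted p = 0.00168, or adjusted p = 0.192 with an estimated correlation). In the deposited glycolysis list, which the study chose, 1 of 48 was higher and none lower.

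**Figure D4:**
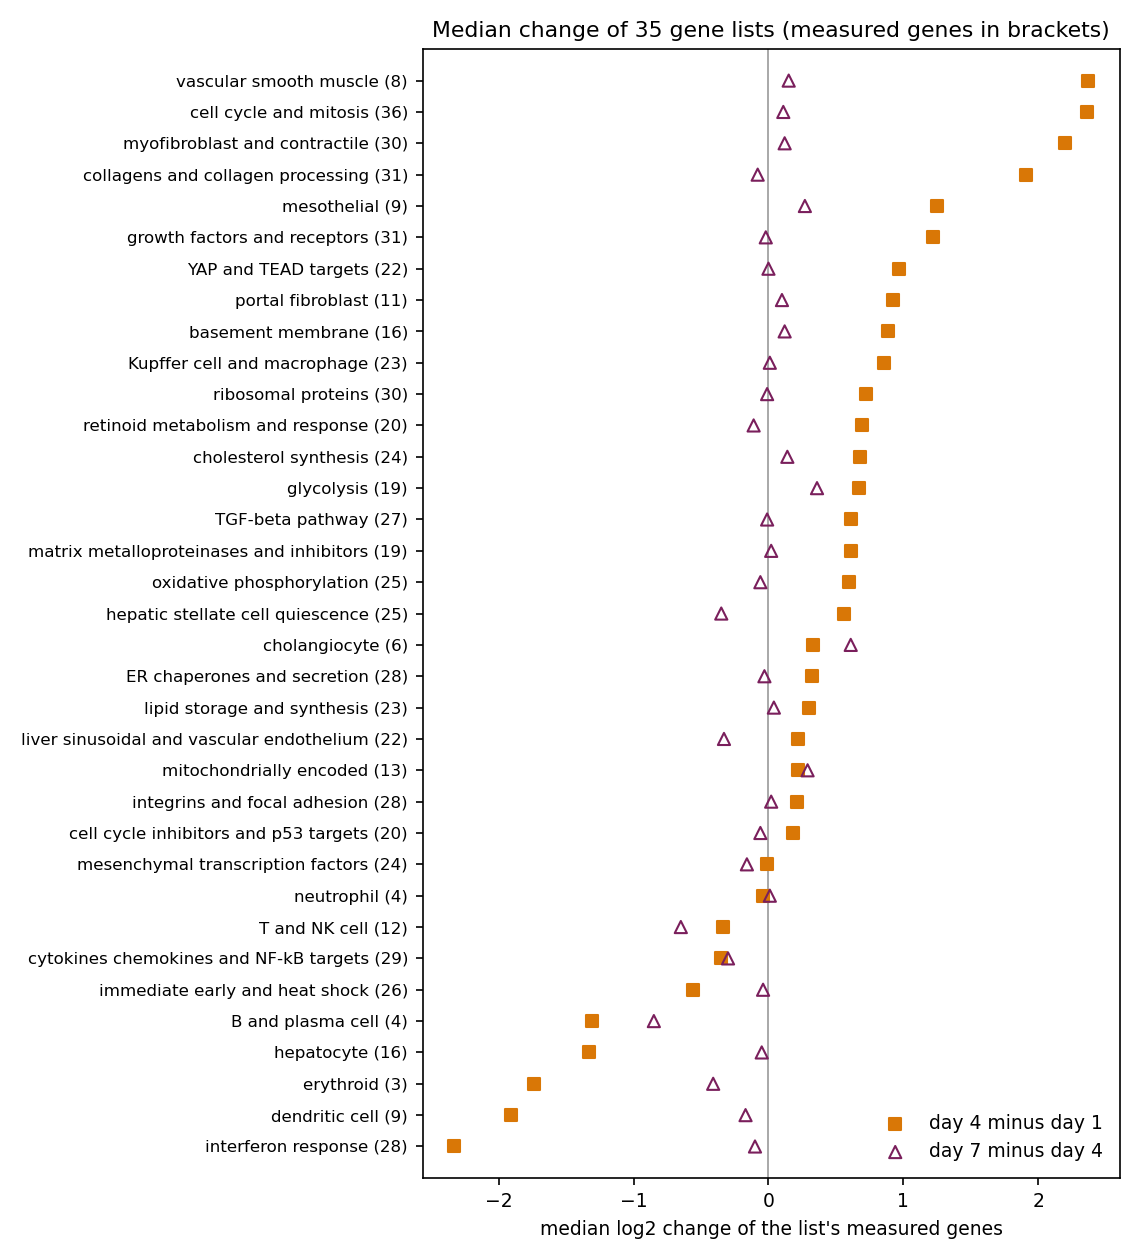
Median log2 change of each of the 35 gene lists on the log2(TPM + 1) scale, with squares for day 4 minus day 1 and triangles for day 7 minus day 4. The interferon response list lies at -2.33 and then -0.1, and the cell cycle list at 2.36 and then 0.11.

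Over all lists, camera at the preset correlation called 19 of 35 between day 4 and day 1, 22 between day 7 and day 1, and 14 between day 7 and day 4. With an estimated correlation it called 0 in each comparison, where 7, 9 and 9 lists had an unadjusted p under 0.05, and fry called 34, 34 and 10.

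Genes such as Acta2, Col1a1 and Rsad2, called between day 4 and day 1, were not called in the later interval, while Col4a5 and Spp1 were. Of the 5257 genes called by day 4, 34 were called again in the same direction between day 4 and day 7, among them Col4a5, Spp1 and Gpnmb rising and Igkc and Cyp1a1 falling. In the reported fit 20 were called in the opposite direction and 5203 were not called in that interval, though some passed in other fits. The median ratio of the day 7 to the day 4 change from day 1 was 1.013, against 0.491 for the top genes of simulated unchanged groups that share libraries in the same way. In the later interval 47.4% of these genes had the opposite sign, against 78.8% in the simulations. The simulations held no changed genes, with a median of 0 called, so they set no expectation for genes that did change. Rising in both intervals were 25 genes, where independent lists of those sizes would share 11, and falling in both were 9 against 2.7. Rising then falling were 8 against 5.7, and falling then rising 12 against 5.1, and part of the excess in these 2 opposite directions may come from the shared day 4 libraries. Both comparisons also used the same spread estimate of each gene, which may raise the overlap in every direction. The excess is therefore not read as continuation. The count of 34 was 245 without day 1 replicate 2, 227 without day 1 replicate 3, and 0 without any one of the 4 later libraries, in which limma left 0 to 4 genes called in the later interval. The moderated F test over the 3 days called 5345 genes, or 3184, 3220, 2755 and 2770 without day 4 replicate 1, day 4 replicate 2, day 7 replicate 1 and day 7 replicate 2.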

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

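Rescaling without the satellite-like models, library weights per day and list tests on only the days compared were chosen after the data were seen. The other alternatives were fixed before the data were examined. Where leaving out a library left 1 on a day, that library was assumed to vary like the other days. Depth is unknown, so its effect on genes of low TPM was not assessed. Tests for read counts were not run, because the table holds TPM. The rescaling planned without mitochondrial, histone and small RNA genes left out 99 genes. The cause of the changes below was not tested unless stated.

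With an absolute log2 change of at least 1, which can only lower a count, limma called 2296 genes between day 4 and day 1, 2689 between day 7 and day 1 and 2883 across the 3 days. Leaving out each library in turn gave 2196 to 7602, 2684 to 7979 and 2755 to 7710 in these comparisons, highest without day 1 replicate 2 and lowest without a library of day 4 or day 7. Every other alternative of these 3 counts stayed within 1.5 times the reported count.

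Between day 7 and day 4 limma called 4 genes with no filter on low values, 37 after quantile normalization, 885 with library weights per day, 609 with only the 2 days compared, and 0 to 546 without each library in turn. The count of genes called again in the same direction was then 1 with no filter, 21 after quantile normalization, 273 with library weights and 0 to 245 without each library. The weights were 0.348 on day 1, 1.885 on day 4 and 1.524 on day 7, so the wider day 1 spread entered the reported fit and not the fit of the 2 later days. The median ratio of the day 7 to the day 4 change was 1.048 after median-ratio scaling, 1.034 after quantile normalization, 1.054 without the satellite-like models and 1.005 to 1.033 without each library, against an SD of 0.0184 between the day 7 libraries.

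Lists called by camera numbered 0 in each comparison with an estimated correlation, where 7, 9 and 9 had an unadjusted p under 0.05, and 34, 34 and 10 by fry. Leaving out each library gave 16 to 23, 18 to 25 and 13 to 15 lists. Of the named genes called, 97 to 113 of 113 kept their call between day 4 and day 1 without each library, and 103 to 115 of 116 between day 7 and day 1. Between day 7 and day 4, 0 or 1 of 27 kept theirs without a later library and all 27 without a day 1 library. Of those 27, 24 kept their call after median-ratio scaling, 18 after quantile normalization and 22 without the satellite-like models. No named gene reversed under any alternative run.

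A replicate block gave 31 genes between day 7 and day 4, with 14 of the 27 named genes keeping their call, and 17 called again in the same direction, with the other counts within 1.5 times. It brought the TGF-beta (camera adjusted p = 0.0476 and 0.0362) and integrin lists (0.00741 and 0.00283) past the threshold between day 4 or day 7 and day 1, and the mitochondrially encoded list (0.000198) between day 7 and day 1. The deviations of replicates 1 and 2 on day 4 and day 7 had a correlation of 0.004 across genes, and day 1 shares only number 2 with them. The values thus showed no pairing by number, but whether libraries with the same number shared a source is unknown.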

Other observations

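The survey of gene families, the test for a larger stellate share, the test of satellite-like reads on the myofibroblast genes and the 3 tests for fewer immune cells were chosen only after the values they concern had been seen. The 2 other tests were fixed before their results, although the number of genes above 0 in each library was already known, and the quiescence test first used the error of single genes, which is not that of a list median, and was then set against a bootstrap interval.

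Tested genes were grouped by the letters that open their symbols, and all 595 such families with at least 4 members were set against the other genes. Between day 4 and day 1, 39 families passed camera at the preset correlation and 0 with an estimated one, where 11 had an unadjusted p under 0.05 (adjusted p = 0.98 for every family named here). Histone genes rose, 56 of 64 with a median log2 change of 2.55 (camera adjusted p = 9.8e-19), and Hist1h1b went from 3.76 ± 0.76 to 116 ± 6.3 TPM. Of the Mcm genes, which include the replicative helicase subunits, 8 of 10 rose and 1 fell (adjusted p = 0.021), and 6 rose without the satellite-like models. Mcm5 rose from 14.2 ± 1.9 to 48.2 ± 0.71 TPM. Between day 7 and day 4 limma called 0 of the 64 histone genes, with 12 at an unadjusted p under 0.05 (median 0.31, camera adjusted p = 6.9e-10, or adjusted p = 1 with an estimated correlation).

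Families of immune and hepatocyte genes were lower on day 4 than on day 1, each with adjusted p = 0.98 with an estimated correlation. Of the H2 genes, which encode antigen-presenting molecules, 15 of 23 fell and 3 rose (median -1.08, camera adjusted p = 2.3e-05), with H2-Aa at 291 ± 20 and 76.8 ± 9.6 TPM. Guanylate-binding protein genes numbered 9 lower and 1 higher of 11 (median -1.68, camera adjusted p = 4.5e-05), and Schlafen genes 7 lower of 8 (median -1.99, camera adjusted p = 1.6e-06), with Slfn4 down from 33.1 ± 0.4 to 0.932 ± 0.083 TPM. All 7 major urinary protein genes, which are hepatocyte products, fell (median -2.58, camera adjusted p = 8.2e-05). Histone, urinary protein and H2 genes include near-identical copies, so values of single members are uncertain. These directions held under the scalings that kept the family.

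A few genes were picked after their values were seen. Olfr1033, an olfactory receptor gene, was at 3980 to 7020 TPM in all 6 libraries. Lars2, a mitochondrial leucyl-tRNA synthetase gene, was at 4700 TPM in day 1 replicate 2 and 130 TPM in day 1 replicate 3, and at 109 to 394 TPM later.

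The 12 satellite-like models were abundant on day 1 and each was 183 to 344 times higher there than later. Genomic DNA in the day 1 libraries is a candidate explanation, since at least 51.7% of the receptor genes were above 0 on day 1 against at most 45.3% later. That test may also reflect depth, which is unknown, since other genes too were more often above 0 on day 1 (59.6% to 60.4% against 55.8% to 57.3%), and receptor TPM without Olfr1033 was only 2.1 times higher on day 1 against 281 times for the models. Transcription of satellite repeats that differs by day stays open and was not tested.

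Myofibroblast genes rose from day 1 to day 4. Of 25 quiescence genes 11 rose with them, such as Des and Lrat, and 4 fell, among them Plin2. A larger share of stellate cell RNA alone would raise both lists alike only if no other cells expressed their genes, which is unknown here. The medians of the 2 lists differed by 1.65 on the log2 scale (bootstrap interval 0.88 to 2.63, 2-sided permutation of genes p = 0.0014, adjusted p = 0.0028 over 4 pairs of lists by the Benjamini-Hochberg method). That difference cannot decide on a larger stellate share, and the scale also understates changes of genes with low TPM. The satellite-like reads lower all other TPM on day 1, but by at most 26.2% in a library, which is too little to give the myofibroblast changes. Rescaling without those models moved the median of all genes only from 0.11 to -0.22. The myofibroblast median of 1.86 after it (bootstrap interval 1.26 to 2.61 over genes), with 24 of 30 still rising, was therefore fixed in advance and adds no support. For the quiescence list as a whole that explanation cannot be told apart, since its median was 0.23 without the models (bootstrap interval -0.41 to 1.07) and 8 members rose while 5 fell. The 8 members that still rose were picked by that same rescaling, so they add no support. A share of at most 26.2% is, however, too little to give the changes of Des and Lrat. A change of cell state by day stays open and was not tested.

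Interferon response genes fell from day 1 to day 4 while markers of several immune cells also changed. A smaller share of macrophage marker RNA is argued against, since 15 of 23 macrophage markers rose and 2 fell, with Clec4f and Lyz2 rising. Marker TPM do not count cells, so the number of macrophages was not measured. The macrophage median lay 3.19 above the interferon median (2-sided permutation of genes p = 2e-05, adjusted p = 8e-05 over the same 4 pairs). That p does not measure the spread between libraries. The test was chosen after both medians were known, so it adds no support. Neither list passed camera with an estimated correlation (adjusted p = 0.519 for macrophages and 0.0838 for interferon). Fewer T and NK cells cannot be told apart from the fall, because although their median lay 2.00 above it (permutation p = 0.019, adjusted p = 0.025), their markers had a median of 3.29 TPM on day 1, under a floor of 5 TPM that was set afterwards. Fewer dendritic cells also cannot be told apart from the fall. The dendritic and interferon medians differed by 0.43 (bootstrap interval -0.39 to 2.14, permutation p = 0.51, adjusted p = 0.51), with Cd74 falling from 962 to 250 TPM. With 9 dendritic genes, the lack of a clear difference is not evidence for a loss of these cells. A response that declined with day stays open and was not tested.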
